A study of Mus musculus with 6 samples.

How the data were processed

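RNA from sorted cells of embryonic mouse dorsal pancreatic buds was sequenced in 6 libraries, 1 for each combination of fraction, stage and genotype present. Per the labels' protocols, the buds were dissociated, Tomato and GFP cells were separated by flow cytometry, frozen fractions were pooled before RNA was purified, and libraries followed standard Illumina procedures. The labels name the control genotype as mTmG alone and do not say how GFP cells were obtained from it.

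The authors deposited 1 table of raw counts per gene for each library, with gene symbols as identifiers. The values are whole numbers and were not normalised, per the files. Table names describe the counts as deduplicated, which lowers the counts of very abundant genes. The submitters' processing notes name the mm10 assembly, Cufflinks 2.2.1 and Cuffdiff 2.2.1. The aligner, the counting program, the annotation and whether counting used strand are not given in the sources used here, so genes that overlap or share sequence with a copy are uncertain. Each table ends with 5 summary lines, which were kept out of library totals. Reads assigned to no gene made up 4.69% to 8.84% of all reads, ambiguous reads 1.53% to 1.72% and reads aligned to several places 13.72% to 20.05%.

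Library totals on genes were 20276045 and 14921268 for the E12.5 epithelium (control and mutant), 14829378 and 15593756 for the E12.5 mesenchyme, and 15513358 and 14032569 for the E14.5 epithelium. Counts were converted to CPM with TMM factors from edgeR 4.0.16 in R 4.3.3, which lay between 0.941 and 1.047. Further work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

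The labels give 1 library per group, so no test across samples was made. A fit of a common genotype effect over the 3 pairs was not used, since it takes differences between fractions and stages as error. The log2 ratio of 2 libraries was given with an exact 95% interval from the conditional binomial distribution (Clopper-Pearson). Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. A gene with no read in 1 library was given a floor of 3 counts in that library and its fold is written as at least that size. Genes were measured at 5 CPM or more in at least 1 of the 2 libraries, and called at 2-fold with an interval that left out 1.

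Gene lists were summarised by the median log2 ratio over their measured members where 3 or more were measured. Each median was set against 10000 random lists of the same size matched on mean log2 CPM in 20 bins, and lists below percentile 2.5 or above 97.5 were said to lie outside the random lists. Of 253 medians, 162 lay outside. Genes in a list vary together, so the percentile describes these libraries and does not measure how often a new pool would give the same value. The lists, comparisons, thresholds and the rule for named genes were fixed before the data were examined. The rule named Pbx2, the 10 genes higher and the 10 lower with the largest fold by the interval bound nearer to 1 among those at 10 CPM or more, without unnamed gene models and sex-linked genes, up to 4 members of each list outside the random lists, and Neurog3, Ins1, Ins2, Gcg, Pdx1, Cpa1 and Nkx2-5. It names more genes than are printed, and those printed were selected from it after their values were seen. Some genes that the rule names are not reported here.

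The calculation was tested on simulated counts drawn from the library means with 200 genes at 10 CPM or more changed. For the E12.5 epithelium genotype comparison (11820 genes in the step), 100% of the genes changed by 1.5 and 100% of those changed by 3 on the log2 scale were called, and 0% of unchanged genes. Such draws hold counting error alone. Gene positions came from GENCODE M21, which uses the same assembly as mm10. Alternatives were size factors from DESeq2 1.42.0, plain CPM, libraries thinned to the smallest total, the 50 most abundant genes left out of the scaling, filters at 1 and 20 CPM or none, thresholds of 1.5-fold and 4-fold, no interval condition, and marker genes left out. Alternatives chosen after seeing the data were ratios relative to the general epithelial genes, leaving out genes higher in mesenchyme, leaving out genes with no read in 1 library, and the acinar median over genes measured in both stage comparisons.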

Results

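Gene expression was measured by RNA sequencing in cells sorted from the dorsal pancreatic buds of mouse embryos. The buds carried the mTmG reporter, whose cells fluoresce red (Tomato) until Cre recombinase switches them to green (GFP). There were 6 libraries, 1 for each group: epithelium at E12.5 and E14.5 and mesenchyme at E12.5, each from control and from Pbx mutant embryos. The mutant genotype includes Cre expressed from the Nkx2-5 locus and 1 mutant copy of Pbx2, which encodes a homeodomain protein that partners with Hox and Meis factors on DNA. The 6 libraries held between 14032569 and 20276045 counts on genes.

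With 1 pooled library per group, no difference below has a replicate check, and no test across samples or p-value is given. Each ratio compares 2 libraries and is given with a 95% interval that covers counting error only. These intervals understate the real error: between the E12.5 epithelial libraries, genes at 5 to 10 CPM (counts scaled to library size) spread with an SD of 0.67 on the log2 scale against 0.18 from counting, and genes at 100 CPM or more with 0.21 against 0.04. A gene is called higher or lower where the ratio was at least 2-fold, its interval left out 1 and it reached 5 CPM in at least 1 of the 2 libraries.

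The genotype ratio of Pbx2 differed between fractions. In E12.5 mesenchyme, Pbx2 stood at 89.9 CPM in the control and 56.0 CPM in the mutant, 1.6-fold lower (interval 1.47 to 1.75). In E12.5 epithelium it was 54.5 CPM in the control and 49.7 CPM in the library labelled mutant. In E14.5 epithelium it was 34.0 and 47.3 CPM, 1.39-fold higher (1.24 to 1.56). At E14.5 the Pbx2 level above the control, and at E12.5 a level 1.1-fold below it, do not show the loss of 1 copy that the label names, so both epithelial libraries are called the libraries labelled mutant, and directions drawn from them rest on that label. Counts over the whole gene need not show a mutant copy that is still transcribed. Control mesenchyme at E12.5 held more Pbx2 than control epithelium (89.9 and 54.5 CPM). At E14.5 general mesenchymal genes summed to 5901 CPM in the control epithelium and 12467 CPM in the library labelled mutant. A difference in cell composition may therefore raise Pbx2 there, which was not tested. In the mm10 assembly Pbx2 lies on chromosome 17 from 34591266 to 34597400, and Nkx2-5 on chromosome 17 from 26838664 to 26845009.

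**Figure D1:**
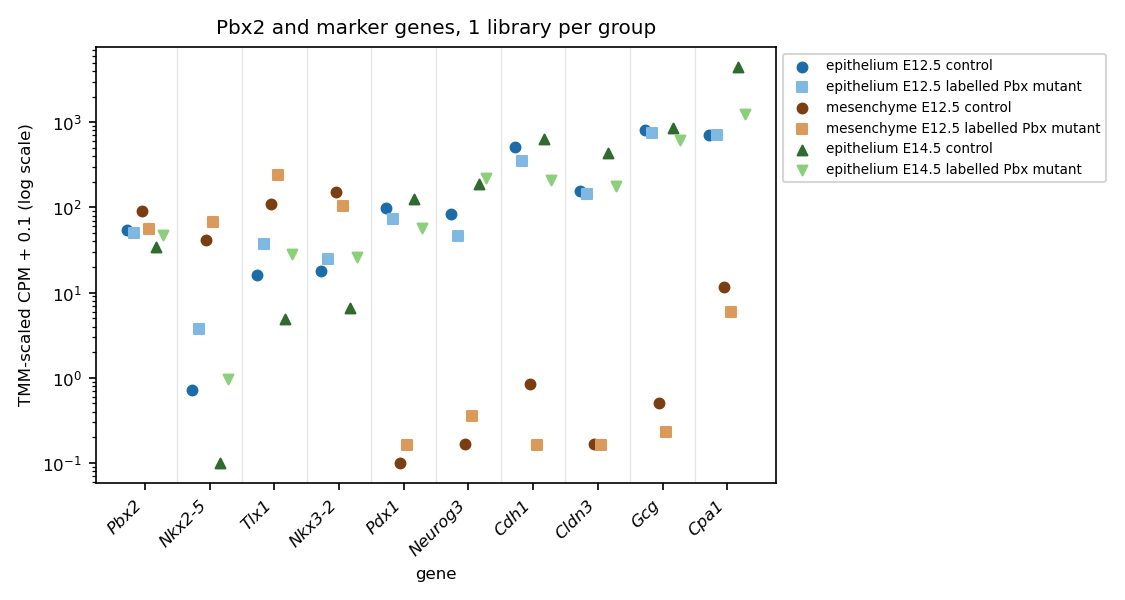
Scaled CPM plus 0.1 on a log axis for Pbx2 and marker genes, with 1 point per library. Pbx2 was lower in the mutant mesenchyme (56.0 CPM) than in the control mesenchyme (89.9 CPM), Nkx2-5 was high in both mesenchyme libraries (41.2 and 66.8 CPM), and Pdx1 was at most 0.0643 CPM in them.

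The first comparison asked how the sorted fractions differed in control embryos at E12.5. The mesenchyme library held the transcription factors of splanchnic mesenchyme, with Nkx2-5 at 41.2 CPM against 0.612 CPM in epithelium (67.4-fold higher, 39.1 to 127), Nkx3-2 8.57-fold higher (7.69 to 9.59) and Tlx1 6.85-fold higher (6.09 to 7.73). The epithelium library held glucagon (Gcg, 802 against 0.402 CPM), the claudin Cldn3 (157 against 0.0671 CPM) and the progenitor factor Pdx1 (99.5 CPM, with no read in mesenchyme, at least 495-fold). In all, 845 genes were higher and 1637 lower in mesenchyme among 12066 measured. Of 25 general epithelial genes 24 were lower in mesenchyme, with a median log2 ratio of -6.84, and all 12 measured acinar genes were lower, with a median of -7.11. Of 29 general mesenchymal genes 21 were higher, with a median of 1.24, and their summed level was 5862 CPM in epithelium and 12897 CPM in mesenchyme. Wnt target genes were higher in mesenchyme (8 of 14 higher, 3 lower, median 1.29), among them Lef1 (6.3-fold, 5.57 to 7.16) and Notum (4.89-fold, 4.16 to 5.78). Markers of other cell types went both ways: 20 of 24 endothelial markers and 21 of 21 leukocyte markers were lower in mesenchyme, with Tie1 and S100a9 at no read there. Of 5 erythroid markers 3 were higher in mesenchyme and 2 lower (median 5.96), and of 13 smooth muscle and pericyte markers 4 were higher (median 0.51).

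In mutant embryos at E12.5 the fractions differed in 648 genes higher and 1541 lower in mesenchyme among 11956 measured. Nkx2-5 was 18.1-fold higher in mesenchyme (13.9 to 24.2) and Kazald1, an insulin-like growth factor binding protein relative, 12.9-fold higher (11.7 to 14.3). Gcg stood at 0.129 CPM in mesenchyme and 741 CPM in the epithelium library labelled mutant, and 24 of 25 general epithelial genes were lower in mesenchyme (median -6.93). Of the 29 general mesenchymal genes 11 were higher (median 0.78). Of 14 smooth muscle and pericyte markers 6 were lower in mutant mesenchyme than in the epithelium labelled mutant (median -0.5), with Acta2 4.26-fold (3.79 to 4.8) and Actg2 7.76-fold (5.77 to 10.6). The 2 fraction comparisons share no library: 294 genes were higher in both against 37.7 for independent lists, and 1157 were lower in both against 178.4.

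The second question was how mutant and control differed in E12.5 mesenchyme, the fraction that expresses Nkx2-5. Among Hox genes, which set position along the body axis, 4 of 17 were called higher in the mutant and 13 neither, with a median log2 ratio of 0.6, above every random list. Hoxa7 stood at 0.939 CPM in the control and 12.7 CPM in the mutant (13.6-fold, 7.89 to 25.3) and Hoxb6 at 33.1 and 126 CPM (3.82-fold, 3.46 to 4.22). Sox9, a factor of ductal and skeletal progenitors, was 4.14-fold higher (3.59 to 4.78), and Six2 and Eya1, known from kidney progenitors, were 4.28-fold (3.58 to 5.14) and 2.32-fold higher (1.92 to 2.8). The secreted proteins Kazald1 (66.9 to 347 CPM) and Cthrc1 (19.9 to 124 CPM) were 5.2-fold (4.85 to 5.56) and 6.23-fold higher (5.51 to 7.06), and the relaxin receptor Rxfp1 went from no read to 16.7 CPM, at least 83.1-fold.

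Matrix and mesothelial lists had medians below 0 in the mutant mesenchyme. The median over 27 collagens was -0.33 and over 41 basement membrane and matrix glycoprotein genes -0.25, both below every random list, although 2 collagens passed the rule as lower and 1 as higher, and 3 of the glycoprotein genes as lower and 2 as higher. Col14a1 was 3.7-fold lower (3.27 to 4.2), Fbln5 2.56-fold (2.2 to 2.98) and fibronectin (Fn1) 2.07-fold (1.85 to 2.32). Among 10 mesothelial markers 4 were lower (median -0.66), with the retinoic acid synthesising enzyme Aldh1a2 at 40.0 and 15.6 CPM and Rspo1 at 5.57 and 0.772 CPM. The guidance cues Sema3d and Slit1 were 9.78-fold (5.83 to 17.5) and 6.95-fold lower (5.07 to 9.74). Of 7 measured genes on the Hedgehog list, Cdon passed the rule (2.93-fold lower, 2.43 to 3.56) and the median was -0.36. That list mixes receptors and co-receptors such as Cdon with target genes, so its median gives no direction of Hedgehog signalling.

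Other cell types also differed between the 2 mesenchyme pools. Of 8 leukocyte markers 7 were lower in the mutant (median -1.8), with Csf1r 6.67-fold lower (4.46 to 10.3), and 3 of 4 erythroid markers were lower, with Hbb-y at 46.2 and 0.643 CPM. Of 27 immediate early genes, which respond to handling, 6 were called lower and 21 neither (median -0.38), with Jun 2.39-fold lower (2.31 to 2.47). In total 219 genes were higher and 392 lower among 11188 measured. Eno1b, listed among the largest differences at 7.47-fold higher (6.22 to 9.02), shares sequence with Eno1, so its counts are uncertain.

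**Figure D2:**
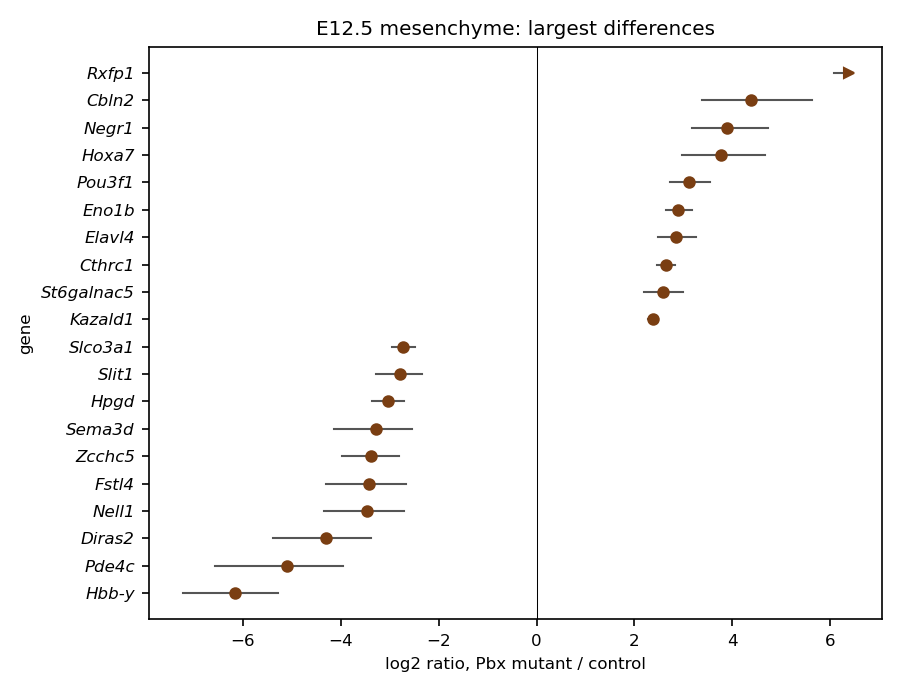
Log2 ratio of Pbx mutant to control in E12.5 mesenchyme for the 10 genes higher and the 10 lower with the largest difference by the nearer interval bound; lines are 95% counting intervals and the triangle marks a lower bound. Kazald1, the most abundant of them in the mutant (347 CPM), was 5.2-fold higher.

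The third question was how the library labelled mutant and the control differed in E12.5 epithelium. Of 22 endocrine transcription factors 5 were called lower and the median was -0.39, or -0.18 relative to the general epithelial genes. Among the 5, Neurod1 was 2.4-fold lower (2.07 to 2.79) and Rfx6 2.08-fold lower (1.72 to 2.52). Neurog3, which starts endocrine differentiation and acts upstream of Neurod1, stood at 82.8 CPM in the control and 45.5 CPM in the library labelled mutant (1.82-fold lower, 1.66 to 1.99), short of the 2-fold threshold. Of 26 hormone and secretory genes 2 were called higher and 1 lower, with a median of -0.22, or -0.01 on the relative scale. Of 21 progenitor transcription factors 1 was called lower and the median was -0.43, with Nkx6-1 1.75-fold (1.63 to 1.87) and Onecut1 1.69-fold lower (1.56 to 1.82), and of 19 Notch genes 1 was called lower (median -0.44), Hey1 being 2.14-fold lower (1.85 to 2.48). Relative to the general epithelial genes these medians were -0.22 and -0.24, Neurod1 was 2.08-fold lower, and Rfx6 (1.8-fold lower), Hey1 (1.85-fold), Neurog3 (1.57-fold), Nkx6-1 (1.51-fold) and Onecut1 (1.46-fold) were below the threshold. Cpa1 (700 and 698 CPM) and Gcg (802 and 741 CPM) were within 1.08-fold of each other. General epithelial genes, which all epithelial cells share, had a median of -0.21 with 1 of 25 called lower.

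Hox genes and splanchnic mesenchyme factors had higher medians in the E12.5 epithelial library labelled mutant. Hox genes had a median of 1.02 with 7 of 14 called higher, among them Hoxa7 (4.22-fold, 3.24 to 5.56). The splanchnic mesenchyme factors had a median of 0.59 with 4 of 21 called higher, with Foxf1 2.61-fold (2.3 to 2.98) and Barx1 2.05-fold higher (1.95 to 2.16). Of 15 smooth muscle and pericyte markers 4 were called higher and 1 lower (median 0.32). Among them Actg2 and Acta2 were 8.41-fold (6.43 to 11.2) and 2.87-fold higher (2.63 to 3.14). Between mutant and control E12.5 mesenchyme 5 of 13 of these markers were lower and 0 higher (median -0.23). Of 28 general mesenchymal genes 2 were called higher (median 0.25), with sums of 5862 CPM in the control and 6670 CPM in the library labelled mutant. Collagens (median 0.02, 2 of 31 lower) lay within the random lists, and leukocyte markers had a median of -0.59 (3 of 22 lower). In all, 215 genes were higher and 385 lower among 11991 measured. Set relative to the median of the general epithelial genes, a choice made after seeing that this list differed, 441 genes were higher and 233 lower.

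At E14.5 the digestive enzyme program of the acinar cells had the lowest median of the lists. All 23 measured acinar genes were lower in the library labelled mutant, with a median log2 ratio of -2.64. Carboxypeptidase A1 (Cpa1) stood at 4464 CPM in the control and 1239 CPM (3.6-fold lower, 3.54 to 3.66), the elastase Cela2a at 83.9 and 4.67 CPM (18-fold, 14 to 23.4) and the acinar factor Ptf1a at 189 and 56.8 CPM (3.32-fold, 3.07 to 3.6). The trypsin genes Prss1 and Try10 were also lower, but belong to a family of near-identical copies that can share reads. Of 25 general epithelial genes 11 were lower too (median -0.95), with E-cadherin (Cdh1) 2.98-fold lower (2.85 to 3.1), as were 13 of 21 progenitor factors (median -1.14), with Pdx1 2.2-fold lower (2.02 to 2.4). Relative to the general epithelial genes the acinar median was -1.69 and the progenitor median -0.18. On that scale Cela2a was 9.28-fold lower, while Cpa1 (1.86-fold), Ptf1a (1.72-fold), Cdh1 (1.54-fold) and Pdx1 (1.14-fold) were lower by less than the threshold.

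Endocrine genes of the E14.5 epithelium went different ways. Insulin genes were lower in the library labelled mutant, Ins1 at 145 and 40.9 CPM (3.55-fold, 3.23 to 3.9) and Ins2 at 405 and 115 CPM (3.52-fold, 3.33 to 3.72), and Iapp was 2.74-fold lower (2.6 to 2.89). Relative to the general epithelial genes they were 1.83-fold, 1.82-fold and 1.41-fold lower, below the threshold. Neurog3 stood at 187 CPM in the control and 223 CPM, short of the 2-fold threshold, and the median of 25 endocrine transcription factors was 0.19. The relative scale raised the median log2 ratio of all genes by 0.95, and on it Neurog3 was 2.31-fold higher. The 33 hormone and secretory genes had a median of -0.48, and of 0.47 when set relative to the general epithelial genes. Ductal genes (7 of 17 lower, median -0.75) had a median of 0.2 on that relative scale. Unfolded protein response genes (7 of 21 lower, median -0.7) included Edem1 3.4-fold (3.17 to 3.64) and Sdf2l1 3.1-fold lower (2.91 to 3.32), and had a median of 0.26 on the relative scale, where Edem1 (1.75-fold lower) and Sdf2l1 (1.6-fold lower) were below the threshold.

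Mesenchymal genes were higher in the E14.5 epithelial library labelled mutant. General mesenchymal genes summed to 5901 CPM in the control and 12467 CPM, with 22 of 29 higher (median 1.36). All 19 measured Hox genes (median 2.02) and 19 of 22 splanchnic mesenchyme factors (median 2.04, 1 lower) were higher, with Foxf1 at 4.25 and 65.6 CPM (15.4-fold, 11.9 to 20.3). Smooth muscle genes were higher (10 of 15, median 1.47), with Cnn1 50.6-fold (25.4 to 118) and Myh11 13.5-fold (9.73 to 19.4), as were 14 of 20 neural and neural crest markers (median 1.42). Pitx1, a factor of the hindlimb and foregut, went from no read to 21.5 CPM, at least 105-fold. Endothelial markers had a median of 0.24, within the range of random lists, and leukocyte markers of 0.48 (3 of 22 higher, 2 lower). The neutrophil granule genes Ltf and Ngp were at 40.9 and 64.8 CPM in the control and at 0 and 1.15 CPM.

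In total 1171 genes were higher and 777 lower at E14.5 among 12145 measured. Set relative to the general epithelial genes, 5941 were higher and 149 lower, so the balance of higher and lower genes depends on which genes serve as the reference.

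**Figure D3:**
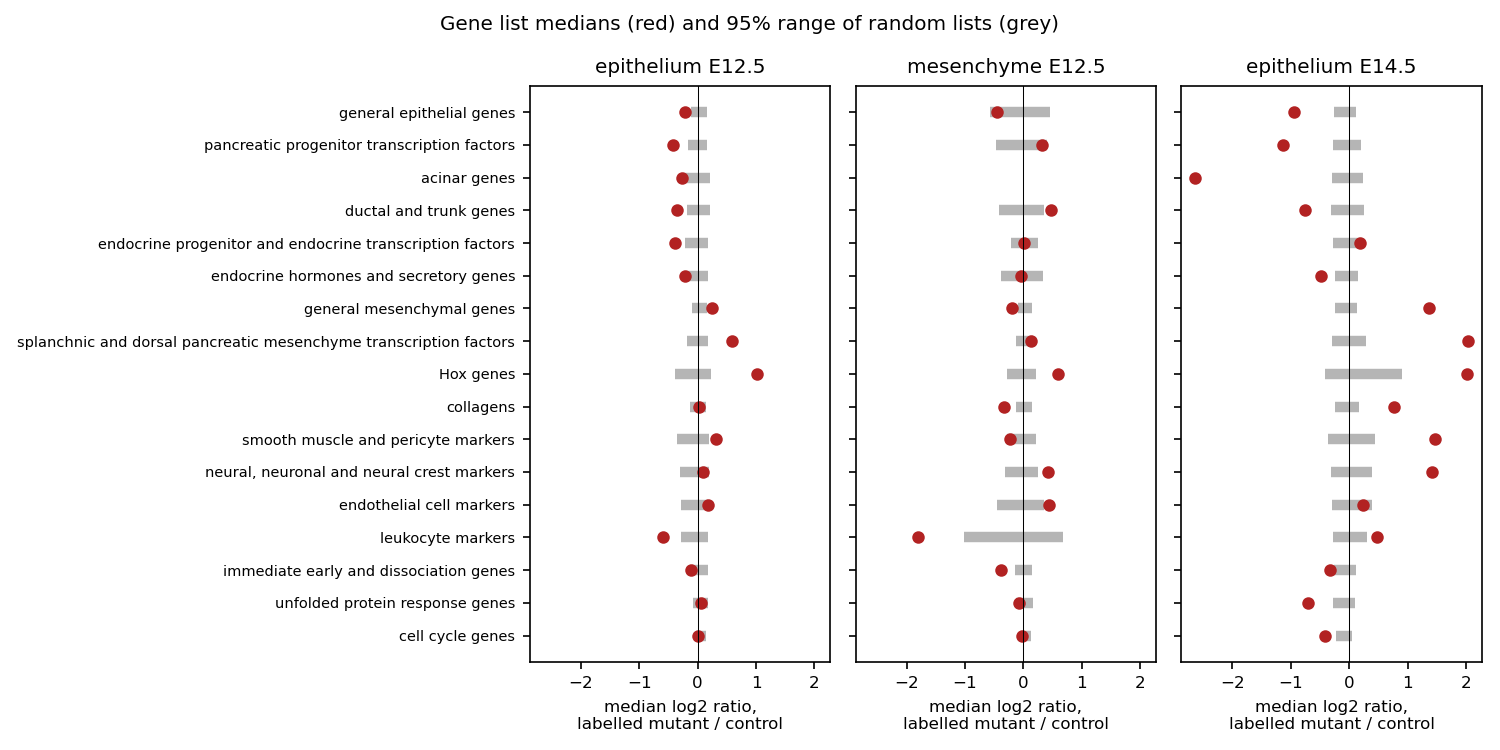
Median log2 ratio of labelled mutant to control for 17 gene lists in the 3 genotype comparisons (red), with the 95% range of medians of 10000 random lists matched on expression (grey). Lists with fewer than 3 measured genes are blank. The acinar median of -2.64 at E14.5 lies lower than the general epithelial median of -0.95, and the Hox medians are above 0 in all 3 panels (1.02, 0.6 and 2.02).

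The next comparison followed control epithelium from E12.5 to E14.5. Acinar genes showed the largest increase of the lists: 22 of 23 were higher at E14.5, with a median log2 ratio of 4.71, and Cpa1 went from 700 to 4464 CPM (6.38-fold, 6.26 to 6.49). Insulin transcripts went from 0.848 to 405 CPM for Ins2 and from 1.7 to 145 CPM for Ins1 (85.5-fold, 61.6 to 122), and 22 of 33 hormone and secretory genes were higher (median 1.46). Neurog3 was 2.26-fold higher (2.13 to 2.4), and Gcg was at 802 and 863 CPM. Of 21 unfolded protein response genes 9 were higher (median 0.83), with Sdf2l1 5.06-fold (4.73 to 5.42), as were 8 of 15 interferon response genes (median 1.02), with Bst2 4.57-fold (3.96 to 5.28).

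Of 28 general mesenchymal genes 11 were lower in the E14.5 control epithelium and 4 higher (median -0.73). The splanchnic factors had a median of -1.67 (14 of 21 lower, 2 higher), and 7 of 20 Notch genes were lower and 3 higher (median -0.55), with Notch2 4.25-fold (3.78 to 4.79). In all, 792 genes were higher and 1355 lower among 12136 measured. Plain CPM moved the median ratio of all genes by -0.15 and the share of higher genes among those called from 36.9% to 24.3%. The name of the deposited table for the E12.5 control epithelium differs in form and date from the other 5, and a difference in sequencing run cannot be told apart from that group in the 3 comparisons that use it.

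The same stages were compared in the epithelial libraries labelled mutant. Of 16 measured acinar genes 13 were higher at E14.5, with a median of 1.96, and Cpa1 went from 698 to 1239 CPM (1.78-fold, 1.73 to 1.82). Fewer acinar genes were measured here than in controls, so the medians over all measured members are not alike. Over the 16 acinar genes measured in both stage comparisons, a set chosen after the data were seen, the median was 4.17 in controls and 1.96 in the libraries labelled mutant, and 16 of 16 had the larger ratio in controls. Neurog3 went from 45.5 to 223 CPM (4.9-fold, 4.51 to 5.33) and Fev from 7.16 to 46.0 CPM (6.43-fold, 5.24 to 7.95), and 12 of 24 endocrine transcription factors were higher (median 1.05). Ins2 went from 0.526 to 115 CPM and Ins1 from 1.18 to 40.9 CPM (34.6-fold, 21.7 to 58.7). General mesenchymal genes had a median of 0.51, with the proteoglycan Lum 14.2-fold higher (12.7 to 16.1), and 4 of 6 skeletal and cardiac muscle markers were higher (median 3.76), Actc1 and Myod1 from no read to 12.4 and 7.18 CPM. In all 763 genes were higher and 717 lower among 12167. The mast cell protease Tpsb2 appeared at E14.5 in both genotypes, from no read to 32.1 CPM in the control and to 48.5 CPM in the library labelled mutant.

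**Figure D4:**
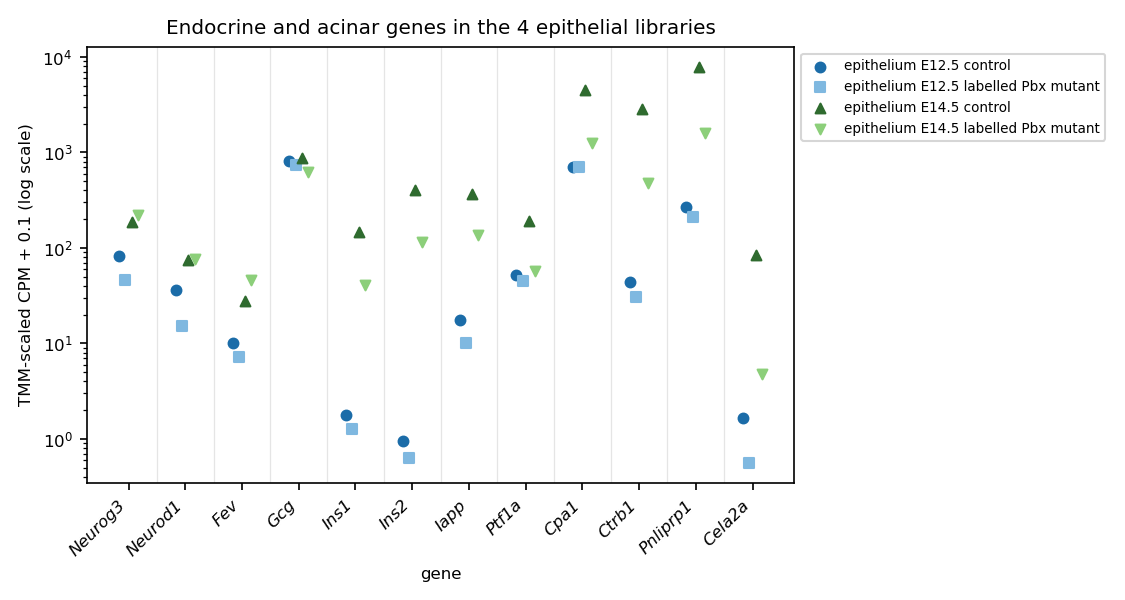
Scaled CPM plus 0.1 on a log axis for endocrine and acinar genes in the 4 epithelial libraries, with 1 point per library. At E14.5 Cpa1 was 4464 CPM in the control and 1239 CPM in the library labelled mutant, while Neurog3 was 187 and 223 CPM.

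The 3 genotype comparisons share no library. Whether the E12.5 fractions came from the same embryos is not given in the sources used here. Across genes, which are not independent replicates, the log2 ratios of the 2 epithelial comparisons correlated with Pearson's r of 0.24 and Spearman's rho of 0.22 (11586 genes), and 77 genes were higher in both against 13.5 for independent lists. In the same pair 65 genes were lower in both against 16.5, and in opposite directions 10 against 8.6 and 36 against 25.9. For the E12.5 epithelium and mesenchyme, 22 genes were higher in both against 2.2, 29 lower in both against 6.1, and in opposite directions 16 against 4.3 and 4 against 3.1. For E12.5 mesenchyme and E14.5 epithelium, 41 were higher in both against 14, 33 lower in both against 9.4, 92 lower and then higher against 25.9, and 21 higher and then lower against 5.1. The E12.5 epithelium and mesenchyme ratios gave 0.16 and 0.21 (10840 genes), and those of E12.5 mesenchyme and E14.5 epithelium -0.09 and -0.08 (10740 genes). The 2 stage comparisons gave 0.51 and 0.46, with 253 genes higher in both against 34.5, and the 2 fraction comparisons 0.89 and 0.67. There were 9 genes called higher and 4 called lower in all 3 genotype comparisons. They were named after their values were seen: Cthrc1, Gm1821, Hddc3, Hoxb8, Kazald1, Lhfpl1, Tlx1, Tmem87a and Wdfy1 were higher, and Fam81a, Lpar2, Paip1 and Sorl1 lower. Kazald1 and Tlx1 are neighbours on chromosome 19, from 45075241 to 45079289 and from 45150680 to 45156943.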

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

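All tests weighed here were chosen after the result they measure was seen. The comparisons listed first are pairs of log2 ratios of opposite sign in 2 comparisons that share no library; each rests on 1 library per group, and the difference between them was not tested.

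Between the E12.5 and E14.5 epithelial genotype comparisons, Neurog3 was -0.86 and 0.25 (difference -1.11) and Pbx2 -0.13 and 0.48 (-0.61). Relative to the general epithelial genes Pbx2 was at 0.07 and 1.43, without opposite signs. The median of leukocyte markers was -0.59 and 0.48 (-1.07). That of hypoxia and glycolysis genes was 0.26 and -0.3 (0.56), but 0.47 and 0.66, without opposite signs, relative to the general epithelial genes. The relative scale moved the median of all genes by 0.21 and 0.95, so such signs depend on the reference.

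Between the E12.5 epithelial and mesenchymal genotype comparisons, medians were 0.62 and -0.36 for the Hedgehog list (difference 0.98) and 0.32 and -0.66 for mesothelial markers (0.98). They were 0.25 and -0.19 for general mesenchymal genes (0.44), and -0.36 and 0.47 for ductal and trunk genes (-0.83).

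Between the E12.5 mesenchymal and E14.5 epithelial genotype comparisons, Pbx2 was -0.68 and 0.48 (difference -1.16). Medians of mesenchymal and matrix lists were -0.19 and 1.36 for general mesenchymal genes (-1.55) and -0.33 and 0.77 for collagens (-1.1). They were -0.25 and 0.63 for basement membrane and matrix glycoproteins (-0.88) and -0.66 and 0.56 for mesothelial markers (-1.22). The Hedgehog list had -0.36 and 1.27 (-1.63). Erythroid markers, with 4 measured genes in each comparison and 2 of them with no read in 1 mesenchyme library, had -5.56 and 1.91 (-7.47), but with no filter the medians were -0.24 and -0.31, without opposite signs. Leukocyte markers had -1.8 and 0.48 (-2.28). The other lists were ductal and trunk genes at 0.47 and -0.75 (1.22), hypoxia and glycolysis genes at 0.19 and -0.3 (0.49), and kidney and urogenital progenitor markers at 0.87 and -0.65 (1.52). Relative to the general epithelial genes the E14.5 medians of these 3 lists were positive, at 0.2, 0.66 and 0.81. The mesenchyme medians were not rescaled, so the 2 sides are on unlike scales. The 5 CPM filter was applied again on the relative scale, so list members, as for the kidney list, can differ.

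Between the fraction comparisons of control and mutant embryos, the median of smooth muscle and pericyte markers was 0.51 and -0.5 (difference 1.01). Between the stage comparisons of control epithelium and of the libraries labelled mutant, Gcg was 0.11 and -0.26 (0.37) and Pdx1 0.34 and -0.35 (0.69). Medians were -0.73 and 0.51 for general mesenchymal genes (-1.24), -0.52 and 0.37 for secreted ligands and antagonists (-0.89), -0.81 and 0.4 for neural and neural crest markers (-1.21), and -0.88 and 0.9 for smooth muscle and pericyte markers (-1.78).

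The E14.5 epithelial library labelled mutant had lower epithelial and higher mesenchymal genes than its control. A lower share of epithelial cells as the whole cause of the acinar difference is argued against by an acinar median 1.69 below that of the general epithelial genes (difference -1.69), the upper quartile of the acinar genes (-2.05) lying below the lower quartile of the epithelial genes (-1.19). The 14 endocrine factors nearly absent from mesenchyme lay above the epithelial genes (difference 1.17). The progenitor factors lay close to them (-0.18), as a lower epithelial share would give for that list. From E12.5 to E14.5 the general epithelial median rose by 0.6 in controls (7 of 25 higher) and by 0.2 in the libraries labelled mutant (0 of 25). Whether cell share or expression per cell changed was not tested, so this list may not measure cell share alone. A rise of all other cell types alike is argued against by a general mesenchymal median 1.11 above the endothelial one. A larger share of mesenchymal cells alone would also give that difference, so it stays open. A different mesenchyme, a delayed or reduced acinar program under the mutant genotype, a dissection difference and a wrong label all stay open, since there is 1 pool per group.

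Mesenchymal genes were present in both E12.5 epithelial libraries. If carry-over of the sorted mesenchymal cells were the whole cause, Nkx2-5 would stand at the same percent of its mesenchyme level as the median general mesenchymal gene, which was 42.3% in the control and 58.3% in the mutant. Nkx2-5 stood at 1.5% and 5.5%, which argues against carry-over as the whole cause. Other factors of this mesenchyme ranged from 11.7% to 63.2%: Tlx1 stood at 14.6% and 15.5%, Nkx3-2 at 11.7% and 23.7%, Barx1 at 19.0% and 63.2%, Tcf21 at 34.9% and 40.9%, and Nkx2-3 at 32.3% and 24.5%. Carry-over as part of the cause stays open, as do mesenchymal cells that never expressed the Cre in the mutant, which were not tested. In controls 20 of 24 endothelial and 21 of 21 leukocyte markers were higher in the epithelial library than in mesenchyme. What such cells add to the general mesenchymal genes was not tested.

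There were 13 genes called in the same direction in all 3 genotype comparisons. Chromosome segments carried along with the Pbx2 and Nkx2-5 alleles are argued against, since 0 of the 13 genes lie within 20 Mb of either locus. A genetic background that differs between the control and mutant stocks cannot be told apart from the genotype: 9 of the 13 genes had 3 log2 ratios within 1 of each other, and stock and genotype coincide. A response to the mutant genotype is a hypothesis that stays open and untested.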

How the results depend on the processing

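Alternatives relative to the general epithelial genes, without genes higher in mesenchyme, without genes with no read in 1 library, and over acinar genes measured in both stage comparisons were chosen after seeing the data. No paired analysis was possible within a comparison because the labels give 1 library per group. A fit of a common genotype effect over the 3 pairs was possible and was not used. Each of the 14 counts of genes stayed within 1.5 times under DESeq2 size factors, plain CPM and thinning. Leaving the 50 most abundant genes out of the scaling or dropping the interval condition also kept them there. So did leaving out marker genes, or genes with no read in 1 library. These 2 removals take out too few genes to move a count that far, so they are no check. Per comparison, 2 to 190 measured genes had no read in 1 library. Leaving out genes higher in mesenchyme kept the 4 counts of the epithelial genotype comparisons within 1.5 times. Only the 294 genes called higher in mesenchyme in both fraction comparisons were left out. Removing all 294 would still keep the 1171 genes higher at E14.5 within 1.5 times, so that count was not checked. Other mesenchymal genes stayed in, so the counts may still hold them. Over the alternatives fixed in advance, 67 values of the 14 counts moved and 87 did not, 58 list medians moved, 8 reversed and 1061 did neither, and 65 named-gene ratios moved and 2939 did not. Depth limits genes near 5 CPM, and no alternative stands in for replicates. Causes were not tested, except that lower filters and thresholds admit more genes by construction.

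Counts are higher then lower. With a 1 CPM filter they were 713 and 944 for E12.5 epithelium by genotype, 626 and 861 for mesenchyme, 1948 and 1272 for E14.5 epithelium. They were 2659 (lower) for control fractions, 1003 and 2570 for mutant fractions, 1403 and 2080 for control stages and 1486 and 1286 for mutant stages. In the same order, a 20 CPM filter gave 44 and 122, 72 and 124, 554 and 445, 540 and 853, 373 and 709, 495 and 709, and 323 and 340. No filter gave 1080 and 1296, 896 and 1155, 2299 and 1518, 1519 and 3120, 1267 and 3077, 1733 and 2491, and 1783 and 1576. A 1.5-fold threshold gave 721 and 1260, 680 and 1012, 2112 and 1804, 1821 (higher), 1659 (higher), 2059 and 2753, and 1566 and 1813. A 4-fold threshold gave 30 and 43, 52 and 71, 255 and 141, 166 and 983, 114 and 906, 216 and 282, and 211 and 99.

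Relative to the general epithelial genes, E12.5 epithelium had 441 and 233 and E14.5 epithelium 5941 and 149. The medians of all genes moved by 0.21 and 0.95, and the 5 CPM filter was applied again, so list members can differ. On that scale the immediate early median became 0.09 at E12.5, and at E14.5 medians became 0.47 for hormones, 0.2 for ductal, 0.55 for cell cycle, 0.66 for hypoxia, 0.26 for unfolded protein response, 0.62 for immediate early, 0.23 for hepatocyte and 0.81 for kidney genes. In the E14.5 genotype comparison the erythroid median was -0.31 without a filter and the hepatocyte median 0.34 at 1 CPM. In control fractions at 20 CPM the interferon median was 0.01 and the neural median 0.76. In mutant fractions the secreted ligand median was -0.15 at 1 CPM and -0.09 without a filter, and the cartilage median 0.32 at 20 CPM and 0.14 without a filter. At 20 CPM the correlation across genes of the E12.5 epithelial ratios was 0.23 with mesenchyme and 0.3 with E14.5 epithelium.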

Other observations

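The mast cell proteases Cma1 and Tpsb2, named here after their values were seen, had reads in the E14.5 epithelial libraries of both genotypes. Cma1 stood at 24.4 CPM in the control and 57.4 CPM in the library labelled mutant, and Tpsb2 at 32.1 and 48.5 CPM, while neither had a read in either mesenchyme library. In the libraries labelled mutant 11 of 23 leukocyte markers were higher at E14.5 than at E12.5 and 2 lower (median 0.95), and 8 of 14 interferon response genes were higher (median 1.09). In control epithelium the leukocyte median was -0.01, while 8 of 15 interferon response genes were higher there too (median 1.02).

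In mutant E12.5 mesenchyme 3 of 8 endothelial markers were higher and 1 lower (median 0.43). Neural and neural crest markers had a median of 0.42, with 2 of 11 called higher and 2 lower. Cartilage and skeletal progenitor markers had a median of -0.45 there (1 of 6 higher, 1 lower).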
